A study of Rattus norvegicus with 6 samples.

How the data were processed

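The series compared young and aged male rats, naive or after an infarct, on 6 single-channel Affymetrix whole-transcript arrays, 1 for each group. Per the labels, total RNA was extracted from microdissected tissue with TRIzol and cleared of DNA with the RNeasy Plus kit, and 200 ng was amplified with the WT Expression Kit and labelled with biotin. RNA of 15 to 23 animals had been pooled for each array, so the spread between animals cannot be seen. The authors deposited 1 value per probe set and array, which was used as a log2 value. The base is inferred from the range of the values and is not stated, and changes and folds depend on it. Per the submitters' processing notes R 2.14.0 and its affy package were used. Background correction, summarisation, normalization and the genome build are not given in the sources used here. From the values, the arrays had been brought to nearly equal medians and upper quartiles, and genes had not been centred. A common scale of this kind removes any overall change in RNA content, and array values compress large folds. No scan date or batch was given, so a batch difference between arrays cannot be told apart from the groups.

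Of 28826 probe sets, 15209 had 1 gene symbol in the platform annotation, 306 had several and 13311 were unnamed here. Of those with 1 symbol, 15178 matched the RefSeq gene table of assembly GRCr8, used for names only, and 0 symbols changed. Probe sets with 1 symbol were kept if they reached the 40th percentile of their array on at least 1 array, and the probe set with the highest mean stood for a gene, which left 10947 genes from 11513 probe sets. Among 399 genes with several kept probe sets, 4 had 1 probe set up at least 2-fold at 3 d and another changed by under 0.2. Genes with near-identical relatives (RT1, Hbb, Slfn, Ifit, Oas) may share probes, so their single values are uncertain.

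Limma 3.58.1 in R 4.3.3 fitted age and time after stroke (naive, 3 d, 14 d) as additive terms over all 6 arrays, leaving 2 residual degrees of freedom, with empirical Bayes variances (prior degrees of freedom 5.56) and Benjamini-Hochberg adjustment at 0.05. This treats the young and aged arrays as repeated measurements of a time effect, and the p-values of genes measure only the spread between these pools. Gene lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over 36 lists. Its p-values set the members of a list against the other genes, taken as nearly independent. They rest on the spread across genes more than on that between pools. Of 37 lists, that of red cell genes had under 5 measured members and was not tested. List members were matched by symbol (919) or synonym (17, for example Fcrl2 for Fcrls), and 135 were unmatched. The correlation estimated by camera rests on 2 degrees of freedom, and with it no list passed in any comparison. Age differences of the response, and lists between single arrays, were not tested. The ages were compared within each matched pair of arrays in an added limma fit that took the other pairs as the error. For single arrays a list's median was set against 10000 random lists of its size, matched in 20 bins of mean expression. Random lists hold unrelated genes, so a list whose genes vary together can fall outside them without any effect of age. The percentiles do not measure the spread between pools.

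The design, the lists and the rule for naming genes were set before the data were examined. For each tested comparison the rule took the 10 largest rises and falls among genes past the threshold with the same direction in each matched pair. Where fewer passed it took up to 5 that did not. Up to 4 members with the largest change were taken per list, and the 5 highest and 5 lowest genes for each untested age difference, among genes at or above the median of all values on at least 1 array concerned. Locus-style names and olfactory or vomeronasal receptors were passed over (49 of the tested genes).

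The functions were tested on simulated arrays with 200 changed genes of 10947, in 20 draws. For 3 d against naive 5.07% of genes changed by 0.5 on the log2 scale were called, 83.2% of those changed by 1 and 99.8% of those changed by 2, and 3.96% of calls were false. For aged against young these were 24.1%, 96.1% and 100%, with 5.45% false. The simulated age difference was equal at all 3 time points, and few genes changed. In the real fit an age difference that varies over time enters the error, and 22.2% of genes were called at 3 d. The shares called and the false shares therefore need not hold for the real arrays. A list shifted by 0.5 at 3 d was found in 20 of 20 draws, and 2 of 700 tests of other lists passed. The simulated genes varied independently, whereas camera's estimated correlation reached 0.671 for the cell division list. The draws therefore do not show how often the list test passes falsely with correlated genes. Alternatives were quantile normalization, median centring, no filter or a stricter filter (60th percentile on 2 arrays), the mean of a gene's probe sets, trended and robust variances, the covariate left out, each array left out, a 2-fold minimum for genes and an estimated correlation for lists. A fit on all probe sets, named or not, was added after seeing the data.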

Results

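RNA levels were measured on Affymetrix rat whole-transcript arrays in brain tissue of male Sprague-Dawley rats after an infarct made by lifting the middle cerebral artery for a time, and in brain tissue of naive rats without a stroke. The 6 groups combined 2 ages with 3 conditions: naive, 3 d after stroke and 14 d after stroke. Tissue after stroke came from the area around the infarct. The labels call the naive tissue healthy brain and do not name its region. Stroke rats were 3 to 4 months old (young) or 19 to 20 months old (aged), and naive rats 3 to 5 or 18 to 20 months. Each group was 1 array of 1 RNA pool, from 19 young or 23 aged stroke rats at each time point and from 15 naive rats of each age. The array medians lay between 7.09 and 7.15 on the log2 scale, and Pearson correlations across all 28826 probe sets between pairs of arrays ranged from 0.962 to 0.995. After filtering, 10947 genes were tested. No group had replicates, and the number of arrays limits the precision: each tested difference rests on the spread between the young and aged arrays about a common effect, which includes any age difference of the response. Errors below are standard errors of log2 changes from that fit, with 2 arrays per time point or 3 per age.

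The first comparison asked which genes differ between tissue around the infarct at 3 d and naive tissue. The largest rise was that of Spp1 (osteopontin), by 5.00 ± 0.24, a 31.9-fold change, with an adjusted p = 5.42e-05. It was followed by Clec7a (the receptor dectin-1, 4.55 ± 0.21), Fcrl2 (an Fc receptor-like gene, 4.52 ± 0.16), Ccl2 (a chemokine that attracts monocytes, 4.52 ± 0.19) and Lgals3 (galectin-3, 4.27 ± 0.18). Next came Timp1 (a metalloproteinase inhibitor, 4.22 ± 0.21), Gpnmb (a glycoprotein of lipid-loaded macrophages, 4.13 ± 0.16), S100a11 (a calcium-binding protein, 4.08 ± 0.24), Hspb1 (a small heat shock protein, 3.80 ± 0.13) and Lcn2 (lipocalin-2, 3.80 ± 0.20). The falls were smaller. Slc17a6, a vesicular glutamate transporter, fell by 2.03 ± 0.24 on the log2 scale, the beta-globin genes Hbb-b1 and Hbb fell by 2.01 and 1.93, and Pmch, the precursor of melanin-concentrating hormone, fell by 1.72. Drd2, a dopamine receptor, changed by -1.46, Shox2, a homeobox transcription factor, by -1.46, and Lrrc10b by -1.45. Tph1 (tryptophan hydroxylase, -1.78 ± 0.48), Calb2 (calretinin, -1.58 ± 0.37) and Slc6a3 (the dopamine transporter, -1.46 ± 0.41) also passed, with adjusted p = 0.0352, 0.0218 and 0.0417. Their falls were mostly those of the aged pair (-2.985, -2.557 and -2.102), against -0.574, -0.611 and -0.824 in the young pair. Pmch, Shox2 and Tph1 reached the 40th percentile, and so the test, through the aged naive array alone. On the stroke arrays they lay below it, and Pmch and Shox2 below the lower quartile, so the size of these falls is uncertain. Slc17a6 (6.363 in young and 6.355 in aged rats) and Slc6a3 (5.8 and 6.141) also lay below the 40th percentile of the 3 d arrays (6.49 and 6.57). Several of the genes that fell are typical of thalamus, hypothalamus, midbrain or pineal gland. In marker lists written after the values were seen, and holding Slc17a6, Shox2, Calb2, Pmch, Tph1 and Slc6a3, the median change at 3 d was -0.309 in young and -0.842 in aged rats for 12 thalamic genes, -0.366 and -0.583 for 7 genes of midbrain monoamine neurons, -0.424 and -0.425 for 9 hypothalamic genes and -0.293 and -0.222 for 5 pineal and pituitary genes, none of them tested. Without the members that the naming rule had already taken, these medians were -0.234 and -0.479 (7 genes left), -0.281 and -0.234 (5), -0.424 and -0.425 (7) and -0.268 and -0.21 (4). In all, 1571 genes were higher and 861 lower with limma, all 2432 in the same direction in the young and in the aged pair of arrays. The fit makes this so and it is no separate support. Opposite changes in the 2 ages count as error, and such a gene could not have passed. The count was 746 without the aged naive array, 1119 without the young naive array, 1050 without the young 3 d array and 3726 without either 14 d array. The calls of Tph1, Calb2 and Slc6a3 ended without the aged naive or the aged 3 d array and with trended and robust variances, and that of Lrrc10b without the aged naive array. Those of Tph1, Slc6a3 and Lrrc10b also ended with age left out of the model.

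Immune and dividing-cell genes rose together at 3 d. Of 37 cell division genes 34 rose, among them Top2a (3.50 ± 0.14), a DNA topoisomerase, and Rrm2 (3.50 ± 0.16), a ribonucleotide reductase subunit, with camera's adjusted p = 1.72e-27. Of 24 genes of phagocytic and lipid-laden macrophages 21 rose (adjusted p = 2.46e-18), of 13 homeostatic microglia genes 11, led by Fcrl2 and the fructose transporter Slc2a5 (2.25; adjusted p = 2.62e-09), and of 12 monocyte and neutrophil genes 11, including Fcgr2b (2.68) and Cd44 (2.56; adjusted p = 1.2e-08). Of 31 interferon-stimulated genes 26 rose, among them Ifi47 (2.44) and Mx1 (2.41; adjusted p = 2.04e-15). Of 26 antigen presentation genes 19 rose, with RT1-DMb at 2.56 and Cd74 at 2.09 (adjusted p = 4.01e-09). Of 18 complement genes 11 rose, with C3ar1 at 2.92 and C1qc at 2.90 (adjusted p = 7.19e-09), and of 24 cytokines and chemokines 14 rose, with Cxcl16 at 2.29 and Il18 at 2.14 (adjusted p = 2.1e-06). Of 11 lymphocyte genes only Cd8a (1.42), Cd8b (1.33) and Cd4 (0.79) passed, and the list did not (median -0.04, mean 0.22, adjusted p = 0.812). The counts of higher genes adjusted over the list alone were 35 for cell division, 22 for phagocytic macrophages, 12 for microglia, 11 for monocytes and neutrophils, 29 for interferon-stimulated genes, 20 for antigen presentation, 12 for complement, 14 for cytokines and 3 for lymphocyte genes. Each of the 8 lists that passed gave adjusted p = 0.305 with an estimated correlation, so that none of their calls held then.

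Glial, matrix and vascular genes rose as well. Of 26 reactive astrocyte genes 20 rose, among them Serpina3n (3.36 ± 0.35), a serine protease inhibitor (adjusted p = 5.72e-16). Of 32 genes of extracellular matrix and scar 27 rose, with Postn (periostin) at 2.58 and Fn1 (fibronectin) at 2.30 (adjusted p = 4.49e-17). Of 29 endothelial and angiogenesis genes 11 rose, with Eng (endoglin) at 1.51 and Tie1 at 1.11 (adjusted p = 0.000197), and of 14 pericyte and smooth muscle genes 7 rose, with Anpep at 2.65 and Tagln at 2.39 (adjusted p = 5.75e-05). Of 17 meningeal genes 9 rose, with Lum (lumican) at 2.10 and Mrc1 at 1.64 (adjusted p = 0.00185). These counts adjusted over the list alone were 20, 30, 11, 9 and 9. All gave adjusted p = 0.305 with an estimated correlation, except the meningeal list, with adjusted p = 0.369 with an estimated correlation.

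Neuronal genes were lower at 3 d, most of all those of the striatum. Of 17 striatal neuron genes 16 fell, with a median of -1.04, including Drd2, the retinoid receptor Rxrg (-1.44 ± 0.12) and the G protein regulator Rgs9 (-1.40 ± 0.17; adjusted p = 5.84e-12). Of 26 glutamatergic neuron genes 9 fell, with Ntng1 at -1.19, and Cux1, named after its value was seen, rose by 0.64 (median -0.32, adjusted p = 2.01e-05). Of 22 GABAergic neuron genes 9 fell, with a median of -0.33 and Calb1 (calbindin) at -1.05 (adjusted p = 4.46e-05). Of 38 voltage-gated ion channel genes 19 fell, including Kcna4 (-1.02) and Scn3b (-0.96; adjusted p = 1.49e-09), and of 31 synaptic vesicle release genes 12 fell, including Syt2 (-0.92) and Unc13c (-0.86; adjusted p = 1.2e-08). Of 12 choroid plexus and ependyma genes 7 fell, with Clic6 at -1.44, Kl at -1.18 and Ttr (transthyretin) at -1.07 (adjusted p = 5.9e-05). Adjusted over the list alone, the lower genes numbered 16, 13, 10, 23, 21 and 9 in these lists. All 6 gave adjusted p = 0.305 with an estimated correlation. The striatal list differed between the naive arrays too, with a median of -0.45 in aged minus young.

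The same question was asked of tissue at 14 d. Clec7a (4.46 ± 0.21) and Fcrl2 (4.21 ± 0.16) were highest, followed by Mx1, an antiviral GTPase, which rose by 4.16 ± 0.14, a 17.8-fold change, with an adjusted p = 5.45e-05. Cd68 (a lysosomal protein of macrophages) rose by 4.14 ± 0.25, Gpnmb by 3.99, Slfn9 by 3.80 ± 0.36, Ifitm1 by 3.69 ± 0.29, Spp1 by 3.67, Usp18 (a protease that removes the interferon-induced modifier ISG15) by 3.62 and Lum by 3.49. On the young and aged naive arrays Usp18 (4.844 and 5.337), Ifitm1 (5.088 and 5.278) and Lum (5.584 and 5.329) lay below the lower quartile (5.69). Mx1 (5.681 and 5.697) lay near it, so the size of these rises is uncertain. The globin genes Hbb-b1 and Hbb fell by 2.84 ± 0.21 and 2.11 ± 0.22, followed by Slc17a6 (-1.82), Pmch (-1.72), Calb2 (-1.62 ± 0.37), Tph1 (-1.60 ± 0.48) and Shox2 (-1.54). Calb2 changed by -1.099 in young and -2.133 in aged rats, and Tph1 by -0.64 and -2.564. Pmch, Tph1 and Shox2 again lay below the 40th percentile of the stroke arrays. So did Hbb-b1 (6.451 in young and 5.61 in aged rats) and Calb2 (6.256 and 6.425) at 14 d, where it was 6.62 and 6.53. Nefm, a neurofilament subunit, fell by 1.53, Tac1, the precursor of substance P, by 1.44 and Lrrc10b by 1.42. The regional lists had medians of -0.47 in young and -0.599 in aged rats for thalamus, -0.126 and -0.606 for midbrain monoamine neurons, 0.042 and -0.665 for hypothalamus and -0.035 and -0.284 for pineal and pituitary genes. Without the members already named they were 0.063 and -0.153, 0.089 and -0.487, 0.042 and -0.665, and -0.024 and -0.27. In all 1491 genes were higher and 1243 lower with limma, each in the same direction in both ages, which the fit again makes so. Without the aged naive array the count was 752 and without the young naive array 1260. With the array medians centred, 1336 were higher and 1686 lower, so that the higher share moved from 54.5% to 44.2%. Lower genes were also the majority with a stricter filter (1346 higher and 1508 lower) and with trended and robust variances (1697 and 1747). The calls of Calb2, Tph1 and Lrrc10b ended without the aged naive array, those of Calb2 and Tph1 with trended and robust variances, those of Tph1 and Lrrc10b with age left out of the model, and that of Tph1 without the aged 14 d array.

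All 31 interferon-stimulated genes rose at 14 d, including Ifi47 (3.00 ± 0.20) and Oas1a (2.65 ± 0.13), with camera's adjusted p = 3.53e-28. Complement genes rose in 14 of 18, with Serping1 at 3.19 and C3 at 3.11 (adjusted p = 2.06e-11), and antigen presentation genes in 20 of 26, with Cd74 at 2.82 and RT1-Da at 2.66 (adjusted p = 9.91e-14). The macrophage list had 21 of 24 higher (adjusted p = 3.76e-16), microglia 12 of 13 (adjusted p = 8.64e-12), monocytes and neutrophils 10 of 12 (adjusted p = 2.51e-06) and cytokines 15 of 24, with Cxcl13, a B cell chemokine, at 3.11 ± 0.38 (adjusted p = 6.95e-09). Among 11 lymphocyte genes Cd4 (2.11) and Cd8b (1.74) rose, as did Cd6 (0.42), named after its value was seen (adjusted p = 0.0261). The other 8 did not pass, and which cells expressed these genes was not measured, so the list does not show that lymphocytes increased. Reactive astrocyte genes rose in 17 of 26, with Cp (ceruloplasmin) at 3.09 (adjusted p = 5.16e-12), matrix genes in 24 of 32, with Bgn at 2.25 and Col1a1 at 2.20 (adjusted p = 7.88e-17), and meningeal genes in 15 of 17, with Igf2, an insulin-like growth factor, at 2.54 (adjusted p = 1.01e-13). Endothelial genes rose in 11 of 29, with Angpt2 at 1.17 (adjusted p = 8.43e-05). In the order given, the higher genes adjusted over the list alone were 31, 14, 23, 21, 12, 10, 15, 3, 19, 26, 15 and 11. All 12 lists gave adjusted p = 0.254 with an estimated correlation.

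Of 37 cell division genes 10 were higher at 14 d, with Aurkb at 1.45 and Top2a at 0.98, and 2 lower: the cyclins Ccne1 (-0.53) and Ccne2 (-0.55), named after their values were seen (median 0.30, adjusted p = 0.000169, and adjusted p = 0.537 with an estimated correlation). Of the neuronal lists, 23 of 31 synaptic vesicle genes fell, led by Syt2 (-1.38 ± 0.14) and Cplx1 (-1.02 ± 0.12; adjusted p = 1.11e-10). Of 38 ion channel genes 26 fell, including the potassium channels Kcnc2 (-0.96) and Kcnc1 (-0.92; adjusted p = 3.72e-11). Lower genes numbered 16 of 17 in the striatal list, with Syndig1l at -1.32 (adjusted p = 1.45e-10), 11 of 26 in the glutamatergic list (adjusted p = 6.33e-06) and 11 of 22 in the GABAergic list, with Pvalb (parvalbumin) at -0.87 and Slc32a1, the vesicular GABA transporter, at -0.85 (adjusted p = 3.3e-07). Adjusted over the list alone, 11 cell division genes were higher and 29, 32, 16, 19 and 16 neuronal genes lower. The neuronal lists had adjusted p = 0.254 with an estimated correlation. Of 12 choroid plexus genes Aqp1 alone passed, at 0.67 ± 0.15, and the list did not (adjusted p = 0.416).

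**Figure D1:**
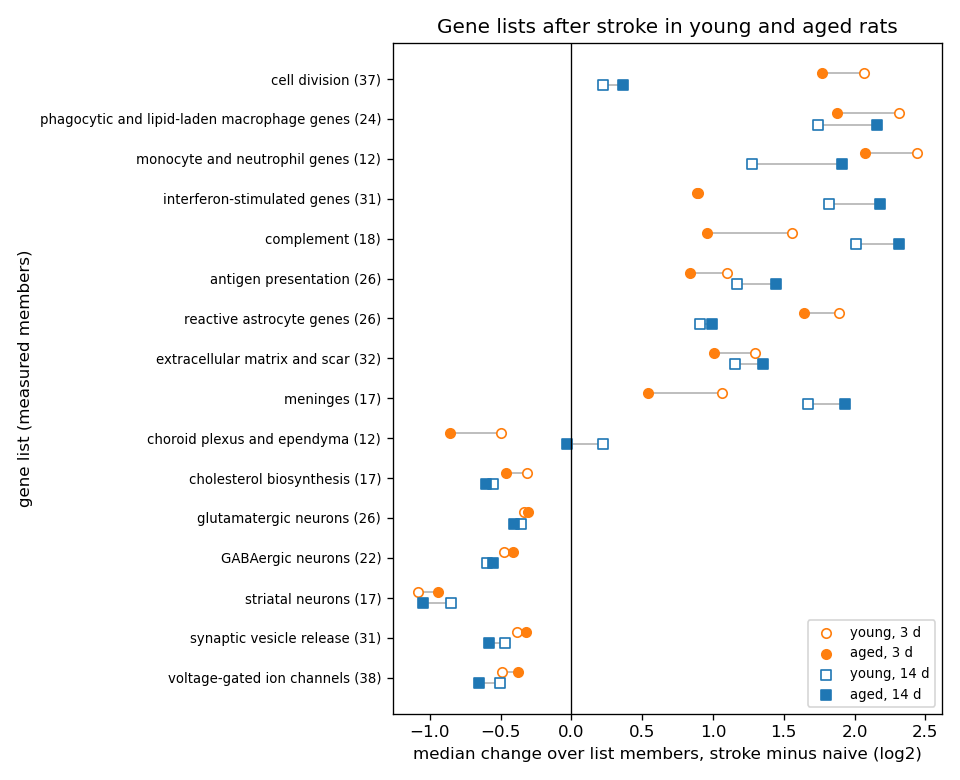
Median log2 change over the measured members of 16 gene lists, stroke minus naive, on the horizontal axis; open symbols are the young and filled symbols the aged pair of arrays, circles 3 d and squares 14 d, with 1 array per group and no error bars. Cell division had medians of 2.07 (young) and 1.77 (aged) at 3 d and 0.22 and 0.37 at 14 d, while the interferon-stimulated list rose from 0.89 in young and aged, where the circles overlap, to 1.82 and 2.18.

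The direct comparison of 14 d with 3 d after stroke used no naive level. Igf2 was higher at 14 d by 2.83 ± 0.14, a 7.13-fold change, with an adjusted p = 0.000523. It was followed by C3, the central complement component (2.20 ± 0.26), Adamts12 (a metalloproteinase, 2.17), Irf7 (an interferon regulatory factor, 1.87 ± 0.12), Gjb2 (a connexin, 1.82), Ifit1 (1.796 ± 0.24), Mfap4 (1.77), Mx1 (1.75), Aox3 (an aldehyde oxidase, 1.74) and Fndc1 (1.68). Rrm2 fell by 3.01 ± 0.16, followed by Serpina3n (-2.64 ± 0.35), Cdkn3 (-2.62), Pbk (-2.54), Lcn2 (-2.54), Top2a (-2.52), Pttg1 (-2.40), Kif20a (-2.36), Ect2 (-2.34) and Ccna2 (a cyclin, -2.32). In all 147 genes were higher and 199 lower with limma, each in the same direction in both ages, which the fit again makes so. The count was 221 without either naive array, 573 without the young 14 d array and 537 without the aged 14 d array. Higher genes became the majority without the young 14 d array (368 higher and 205 lower) and without the young 3 d array (167 and 117). The calls of C3 and Serpina3n ended when age was left out of the model (adjusted p = 0.0704 and 0.0771), and that of Serpina3n also with trended and robust variances.

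Of 37 cell division genes 33 fell from 3 d to 14 d, with a median of -1.59 (camera's adjusted p = 2.7e-58). Interferon-stimulated genes rose in 19 of 31, with Rsad2 (viperin) at 1.63 ± 0.13 (adjusted p = 1.83e-41). Meningeal genes rose in 11 of 17, including the transporters Slc22a6 (1.62 ± 0.14) and Slc6a13 (1.42 ± 0.21; adjusted p = 6.31e-22), and choroid plexus genes in 6 of 12, with Kcnj13 at 1.42 and Ttr at 1.17 (adjusted p = 1.13e-13). Lymphocyte genes had Cd4 higher, by 1.32 ± 0.14, as the only one of 11 (adjusted p = 0.000402). Which cells expressed it was not measured. Adjusted over the list alone, the counts were 37, 30, 14, 9 and 3. These 5 lists had adjusted p = 0.447 with an estimated correlation. Of 26 reactive astrocyte genes 8 fell, including Hspb1 (-1.71) and Emp1 (-1.57), and 2 rose (9 and 3 adjusted over the list alone; adjusted p = 3.55e-05, and adjusted p = 0.571 with an estimated correlation). Matrix genes went both ways, with 5 of 32 higher and 5 lower: Lum (1.40), Ogn (1.33) and Col1a2 (1.33) rose and Postn fell by 1.40 (10 and 9 adjusted over the list alone; median -0.04, mean 0.00, adjusted p = 0.586). Of the neuronal lists, no member of the glutamatergic, GABAergic, striatal, synaptic vesicle or ion channel lists passed with limma over all genes or adjusted over the list alone. The synaptic vesicle list (median -0.11, adjusted p = 0.0111) and the GABAergic list (median -0.13, adjusted p = 0.0356) were lower as lists, with adjusted p = 0.571 with an estimated correlation, and lost their calls without the aged 3 d or the aged 14 d array. That of the synaptic vesicle list also ended with quantile normalization applied again.

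Aged and young rats were compared over the 3 matched pairs of arrays. No gene passed with limma: 0 of 10947 had an adjusted p under 0.05 and 852 had an unadjusted p under 0.05. The largest differences in the same direction at all 3 time points were therefore not past the threshold. They were higher in aged rats for Slfn9 (1.003 ± 0.29), C3 (0.90 ± 0.21), Hormad1 (0.89 ± 0.16), Zfp36 (0.85 ± 0.20) and Hapln2 (0.84 ± 0.21), and lower for Serpina3n (-0.98 ± 0.28), Lrrc10b (-0.96 ± 0.20), Fam111a (-0.75 ± 0.31), Adcyap1 (-0.67 ± 0.17) and Lage3 (-0.64 ± 0.17), with adjusted p from 0.63 to 0.637. In the naive, 3 d and 14 d pairs the differences were -0.12, -1.905 and -0.22 for Fam111a and -0.222, -1.986 and -0.743 for Serpina3n. Those of Hapln2 were 0.089, 1.183 and 1.241, and those of Slfn9 0.372, 0.558 and 2.078. Adcyap1, Lage3, Zfp36 and Lrrc10b also differed least in the naive pair (-0.121, -0.115, 0.266 and -0.515). C3 differed most there (1.617, 0.494 and 0.584), and Hormad1 by 1.119, 0.407 and 1.146. Under other settings 0 to 2 genes passed: Fxyd1 with trended and robust variances, Hormad1 and RT1-Da without either 3 d array, and Oxt without either 14 d array. These 4 were named after their values were seen, except Hormad1.

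As lists, immune genes were slightly higher and neuronal genes slightly lower in aged rats, although none of their members passed over all genes. Interferon-stimulated genes had a median of 0.25 (camera's adjusted p = 9.77e-12), with Gbp2 at 0.53 ± 0.12. Complement had a median of 0.27 (adjusted p = 1.1e-07), antigen presentation 0.23 (adjusted p = 5.69e-07), microglia 0.18 (adjusted p = 5.74e-06) and phagocytic macrophages 0.21 (adjusted p = 0.000166). Striatal neuron genes had a median of -0.38, with Adora2a at -0.63 ± 0.11 and Drd2 at -0.59 ± 0.10 (adjusted p = 1.87e-14), ion channels -0.15 (adjusted p = 1.33e-07), and glutamatergic neurons -0.13 (adjusted p = 7e-04). Adjusted over the list alone, 13 of 17 striatal, 3 of 38 ion channel and 3 of 18 complement genes passed, and 0 in the other 5 lists. The 8 lists had adjusted p = 0.546 with an estimated correlation. The immune differences were not even over time: aged minus young, the medians in the naive, 3 d and 14 d pairs were 0.19, -0.008 and 0.57 for complement, 0.17, 0 and 0.49 for antigen presentation, 0.21, -0.025 and 0.36 for phagocytic macrophages, 0.25, 0.10 and 0.38 for microglia and 0.20, 0.11 and 0.51 for interferon-stimulated genes. Those of striatal genes were -0.45, -0.16 and -0.53. Without either 14 d array the pooled medians were 0.095 for complement, 0.137 for antigen presentation, 0.092 for phagocytic macrophages and 0.165 for interferon-stimulated genes, and without either 3 d array 0.44 for complement, 0.325 for phagocytic macrophages and 0.274 for microglia. The macrophage median was 0.093 without either naive array, and all of these lists stayed past the threshold without any 1 array. With time left out of the model 10 lists passed in place of 23, and the calls of microglia and phagocytic macrophages were among those that ended.

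How far the 2 ages responded alike was measured across genes, on pairs of arrays with none in common. Genes are not independent replicates, and 4 correlations of a young with an aged change were computed. The aged minus young differences were also correlated with each other. These gave r = 0.016 for naive with 3 d, 0.111 for naive with 14 d and 0.274 for 3 d with 14 d. The changes from naive correlated at r = 0.883 between young and aged rats at 3 d and at r = 0.836 at 14 d. Across time points the young 3 d change correlated with the aged 14 d change at r = 0.783, and the aged 3 d with the young 14 d change at r = 0.736. The slope of the aged on the young change was 0.827 at 3 d and 1.06 at 14 d.

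The age difference of the response, the change in aged minus the change in young rats, rests on 1 array per group and was not tested. The differences at 3 d and 14 d share both naive arrays. At 3 d it was lowest for RT1-Da (-2.43; 3.26 in young and 0.83 in aged), Tph1 (-2.41), Cd74 (-2.41; 3.30 and 0.89), Th (tyrosine hydroxylase, -2.15) and Calb2 (-1.95), all of which were higher in the aged than in the young naive pool. It was highest for Eml5 (1.18), Plekhn1 (1.16), Fcho1 (1.10), Rtbdn (1.10) and Hapln2 (1.09). At 14 d it was highest for Lilrb4, an inhibitory leukocyte receptor (2.88; 1.26 in young and 4.14 in aged), Aim2, a DNA sensor of the inflammasome (2.15), Slfn4 (1.88), Cd200r1 (1.86) and Cxcl13 (1.84; 2.19 and 4.03). It was lowest for Scn7a (-2.27), Th (-2.22), Slc6a3 (-2.17), Tph1 (-1.92) and Slc9a4 (-1.55), all again higher in the aged than in the young naive pool. On the 14 d arrays Th stood at 6.562 in young and 6.352 in aged rats, against 6.973 and 8.982 in the naive pools.

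As lists at 3 d, the aged change lay below the young one for matrix genes (median -0.33, 30 of 32 genes), phagocytic macrophages (-0.31, 21 of 24), meninges (-0.31), cell division (-0.26, 34 of 37), choroid plexus (-0.43), brain ageing genes (-0.28, 26 of 28) and oxidative stress genes (-0.24, 25 of 32), each at or below the percentile of 0.02 among 10000 random lists of the same size and mean expression. The median of all genes was -0.06. The 3 d arrays themselves differed for matrix (median -0.39 in aged minus young), cell division (-0.36) and meningeal genes (-0.27), while the naive arrays differed by -0.08, -0.07 and -0.02. For phagocytic macrophages the 3 d arrays differed by -0.025 and the naive arrays by 0.21, so that the smaller aged change went with a higher aged naive level. The same held for brain ageing genes (-0.05 at 3 d and 0.23 naive) and oxidative stress genes (-0.06 and 0.16), and choroid plexus genes differed at both (-0.18 and 0.25). The aged change lay above the young one, and so was the smaller fall, for striatal neuron genes (median 0.21, 14 of 17 genes), ion channels (0.075, 26 of 38) and glutamatergic neurons (0.04, 14 of 26), with percentiles from 99.33 to 100. All 3 of these lists were lower in the aged naive array. Lists of general function lay below at 3 d as well, the respiratory chain with a median of -0.19 (percentile 0.12), reference genes with -0.19 (percentile 2.11) and ribosomal proteins, a group chosen after its values were seen, with -0.214. In all, 14 of 36 lists lay below and 3 above the central 95% of random lists at 3 d, and 12 below and 6 above at 14 d. Genes of a list vary together and random ones do not, so these counts do not show an effect of age. At 14 d the aged change lay above the young one for monocyte and neutrophil genes (median 0.68, 10 of 12 genes), interferon-stimulated genes (0.36, 26 of 31), apoptosis and pyroptosis genes (0.33, 21 of 30), complement (0.29, 16 of 18), antigen presentation (0.22, 19 of 26) and cell division (0.18, 29 of 37), with percentiles from 99.19 to 100. It lay below for pericytes (-0.25), axon growth genes (-0.21) and reactive astrocyte genes (-0.19), with percentiles from 0 to 0.24. Striatal neuron genes, above at 3 d, lay below at 14 d (-0.21, 11 of 17 genes, percentile 0.38; -0.85 in young and -1.05 in aged rats). For reactive astrocyte genes the median of the differences and the difference of the medians went apart, since the median change was 0.91 in young and 0.99 in aged rats. The globin genes Hbb and Hbb-b1 were lower in the aged than in the young 14 d array, by -0.39 and -0.84.

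**Figure D2:**
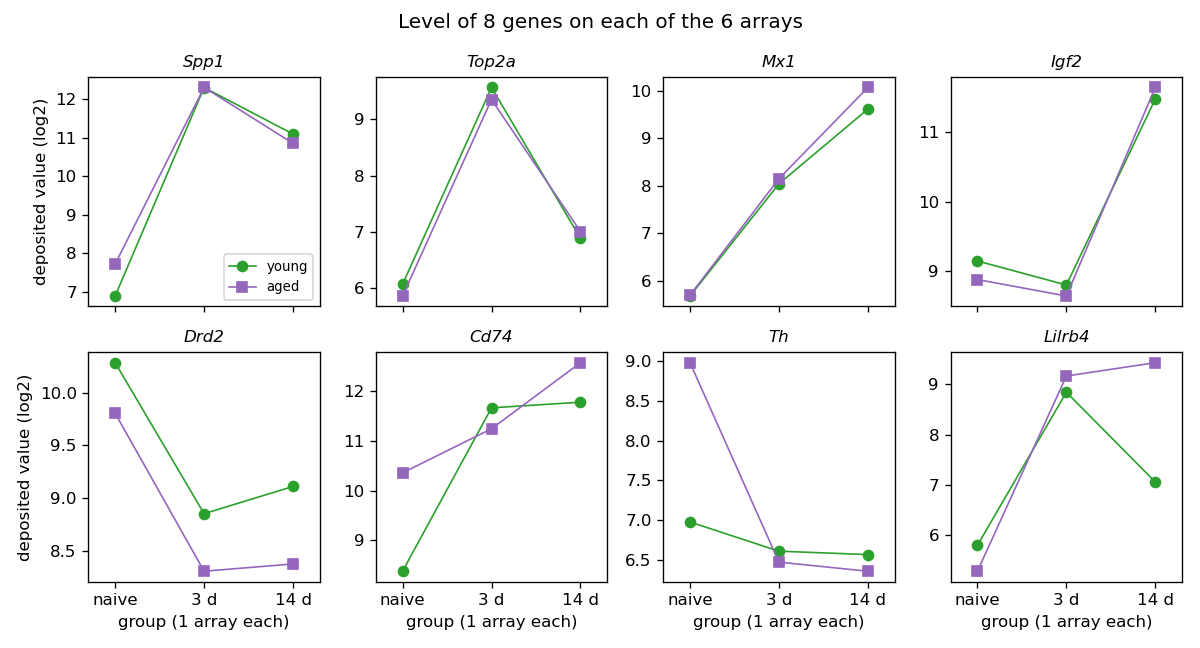
Deposited log2 value of 8 genes on each of the 6 arrays, by group on the horizontal axis; circles are young and squares aged rats, each point is 1 array of 1 pool, and the vertical axes differ between genes and do not start at 0. Lilrb4 stood at 8.84 and 9.16 at 3 d in young and aged rats and at 7.06 and 9.43 at 14 d, while Th stood at 6.97 in the young and 8.98 in the aged naive pool and between 6.35 and 6.61 after stroke.

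Naive aged and naive young tissue, 1 array each, differed in 0 genes past the threshold with limma when the age differences at 3 d and 14 d were taken as the error, and in 74 at an unadjusted p under 0.05. The largest differences were those of Tph1 (2.38 higher in aged), Th (2.01), Cd74 (1.99), Slc6a3 (1.62) and C3 (1.62). Lowest in aged were Gpr149 (-0.79), Hbb-b1 (-0.65), Lpar6 (-0.61), Drd1 (-0.61) and Rgs9 (-0.59). In lists, microglia genes had a median of 0.25 (12 of 13 higher), phagocytic macrophages 0.21, interferon-stimulated genes 0.20 and complement 0.19 (16 of 18), each at the 100th percentile of the random lists. Choroid plexus genes were at 0.25 (10 of 12 higher). All 17 striatal genes were lower (median -0.45), as were 33 of 38 ion channel genes (-0.18), each at a percentile of 0.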

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

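All tests in this part were chosen after the results were seen.

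Some genes named for their age difference changed in opposite directions in young and aged rats, which was not tested since each group was 1 array. At 3 d these were Eml5 (aged minus young change 1.18), Plekhn1 (1.16), Fcho1 (1.10), Rtbdn (1.10) and Hapln2 (1.09), each lower after stroke in young and higher in aged rats. At 14 d they were Cd200r1 (1.86) and Slc9a4 (-1.55). Their naive levels differed too, at 6.841 in young and 6.141 in aged rats for Cd200r1 and 6.192 and 7.279 for Slc9a4. The median changes of the axon growth, neural progenitor and choroid plexus lists at 14 d were above 0 in young and below 0 in aged rats, with median age differences of -0.21, -0.13 and -0.18, also not tested. Probe sets without a gene name here also differed in a fit on all probe sets: 554 passed at 3 d against naive, 686 at 14 d and 67 between 14 d and 3 d, out of 7126 unnamed.

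The first pattern weighed was the fall of striatal neuron genes. At 3 d their median lay below that of the 48 genes of the glutamatergic and GABAergic lists. The difference was -0.716 (-0.673 in young and -0.622 in aged rats). In each age the upper quartile of the striatal genes (-0.888 and -0.741) lay below the lower quartile of the others (-0.544 and -0.633). At 14 d the quartiles overlapped in aged rats. The striatal genes thus fell more at 3 d than most of the others. This cannot decide on an equal loss of all neuron types, as the share of each gene's RNA from neurons was not measured. The glutamatergic list also held a gene that rose. An equal loss therefore stays open. Different shares of brain regions in the dissected pools may contribute: the striatal list also differed between the naive arrays, by -0.448, outside the central 95% of random lists. Regional marker lists were written around genes already seen to differ, so they are no test: without the members that the naming rule had taken the medians of aged minus young naive were 0.268 for thalamus (6 of 7 genes higher), 0.46 for midbrain monoamine neurons (5 of 5), 0.231 for hypothalamus (6 of 7) and 0.15 for pineal and pituitary (4 of 4), against 0.341, 0.513, 0.247 and 0.196 with them. Loss of striatal neurons around the infarct and an effect of age on these genes stay open, untested.

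The second pattern was the rise of meningeal genes from 3 d to 14 d. Growth of scar matrix as a whole would have raised other matrix genes too. The 27 outside the meningeal list had a median of -0.149 and the 12 meningeal genes outside the matrix list 0.971. The difference was -1.12 (-1.182 in young and -1.293 in aged rats). The upper quartile of these matrix genes (0.064 and 0.381) lay below the lower quartile of the meningeal genes (0.403 and 0.593). Matrix genes thus did not rise as a set, nor with the shared genes included (median -0.035). The split left out shared genes that rose, such as Lum (1.016 in young and 1.778 in aged rats). The meningeal list was the one whose rise defined the pattern. Growth of a part of the matrix therefore stays open. More meningeal and plexus tissue in the 14 d pools is consistent with the choroid plexus list, which rose by a median of 0.747, by 0.572 in young and 1.04 in aged rats, above all 10000 random lists. The abundant plexus transcript Ttr stood at 11.27 and 11.34 at 3 d and 12.41 and 12.53 at 14 d, near its naive 12.19 and 12.55, while Igf2 exceeded its naive level. Of the 17 meningeal genes 5 are also in the matrix list, and growth of meningeal cells after stroke stays open, untested.

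The third pattern was the higher level of innate immune genes in the aged 14 d pool. A uniformly larger response stays open: of 19 lists that rose at 14 d, 6 had an age difference above and 3 below the central 95% of random lists, but reactive astrocyte genes (median -0.187) had a larger median rise in aged (0.992) than in young rats (0.912), these and brain ageing genes (-0.13) were higher in the aged naive array, and only pericyte genes (-0.249) had neither limit. More blood in that pool stays open too. Globin genes were lower in aged than in young rats at 14 d (median -0.618), but about as much in the naive arrays (-0.586). This leaves a median of -0.032 over 2 genes (0.124 for Hbb and -0.189 for Hbb-b1). The standard deviation of such a difference, from the error of the fit, was 0.437. Across genes the aged minus young difference at 14 d correlated with the young 3 d change at r = 0.459. Over all probe sets the aged 14 d array was closer to the aged 3 d array (r = 0.9888) than to the young 14 d array (r = 0.9829). An effect of age, the time course of the 2 ages and chance differences of 1 array may each account for the pattern as well, and none of these can be told apart here with 1 array per group.

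Over all time points 0 genes passed between aged and young arrays with limma, and 852 had an unadjusted p under 0.05. The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and all 10 reach the real count of 0 by construction, so the splits bear on chance in neither direction. The highest other split gave 46. With time in the model, each of the 6 splits that part 1 matched pair compares the ages within that pair alone, and both splits with 46 genes are the contrast of aged and young rats at 14 d. The 3 other splits that part all 3 pairs gave 0. All 46 genes were higher in the aged 14 d array, among them Lilrb4 (2.37), Slfn4 (1.95), Cxcl13 (1.82) and Aim2 (1.799), and 2344 had an unadjusted p under 0.05, while the naive pair gave 0 genes (74 unadjusted) and the 3 d pair 0 (293 unadjusted). These limma fits take the age differences of the other pairs as error, assume that a lone array varies like the others and compare 1 pool of each age. The standard deviation of the age difference across genes was 0.336 at 14 d, 0.173 in the naive pair and 0.22 at 3 d. The naive and 3 d fits thus hold the wider 14 d difference in their error, and their counts are not comparable with that at 14 d.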

How the results depend on the processing

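The fit on all probe sets was chosen after seeing the data, the other alternatives before. Of 60 named genes past the threshold 51 kept their call and direction in every alternative run, and so did 65 of 97 list calls, leaving aside the estimated correlation. With a 2-fold minimum 700 genes passed at 3 d, 685 at 14 d and 176 between 14 d and 3 d, fewer by construction. With an estimated correlation 0 lists passed in each of the 4 comparisons. This setting changes both the correlation and the degrees of freedom. The estimate lay below the preset 0.01 for GABAergic (-0.019) and lymphocyte genes (-0.093). Camera's adjusted p still went from 3.3e-07 to 0.254 for GABAergic genes at 14 d against naive. For lymphocyte genes at 14 d against 3 d it went from 0.000402 to 0.447. A higher correlation thus did not end these calls. What ends the other calls was not tested. Leaving out 1 array gave 746 to 3726 genes at 3 d, 752 to 3470 at 14 d, 221 to 573 between 14 d and 3 d and 0 to 2 between ages. A lone array is then assumed to vary like the other groups, and 1 residual degree of freedom is left. Lists past the threshold numbered 25 to 27, 26 to 28, 14 to 22 and 18 to 22 in these fits. With trended and robust variances 1 gene passed between ages, and with time left out 10 lists did; the cause was not tested. Without 1 array the median of the cell division list between ages ranged from -0.219 to 0.038 (main -0.10), turning without either 3 d array, and that of the phagocytic macrophage list between 14 d and 3 d from -0.416 to 0.033 (main -0.16), turning without the young 3 d array. Neither list was past the threshold where it turned, and the cause was not tested. Other medians between 14 d and 3 d also fell below 0 in some alternative. The lowest was -0.056 for complement (main 0.31) and -0.035 for homeostatic astrocyte genes (main 0.041). Correlations of the young and aged changes stayed between 0.847 and 0.908 at 3 d and between 0.789 and 0.878 at 14 d. No pairing beyond that of the model was possible because each group held 1 array. The comparison of ages, with time as a term, already sets the matched arrays of each time point against each other. The comparisons of time points hold age as a term in the same way. Signal over background could not be assessed, as no background value was used here.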

Other observations

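Genes of cholesterol biosynthesis and of cholesterol efflux moved apart after stroke, and the respiratory chain list was slightly lower. Cholesterol biosynthesis genes fell in 7 of 17 at 3 d and 12 of 17 at 14 d, when Fdft1 (squalene synthase) fell by 1.18 ± 0.12, Idi1 by 1.17 and Insig1 by 1.16 (8 and 14 adjusted over the list alone; camera's adjusted p = 8.22e-05 and 2.23e-07, and adjusted p = 0.321 and 0.254 with an estimated correlation). Genes of cholesterol efflux and lipid storage rose in 11 and 13 of 19, with Plin2, a lipid droplet coat protein, at 2.42 ± 0.26 at 3 d and the cholesterol exporter Abca1 at 2.13 ± 0.15 at 14 d (13 and 15 adjusted over the list alone; adjusted p = 6.22e-07 and 1.84e-07, and adjusted p = 0.305 and 0.254 with an estimated correlation). Of 43 respiratory chain genes Ndufs3 alone fell at 3 d, by 0.47, and 6 fell at 14 d, with list medians of -0.18 and -0.25 (0 and 2 adjusted over the list alone; adjusted p = 0.000873 and 7.31e-06, and adjusted p = 0.526 and 0.418 with an estimated correlation). The list's call at 3 d ended without the aged naive array (adjusted p = 0.0527). Oxidative stress genes rose in 14 of 32 at 3 d, with the NADPH oxidase subunit Cybb at 3.37 and Hmox1 at 2.41 (15 adjusted over the list alone; adjusted p = 4.46e-05, and adjusted p = 0.305 with an estimated correlation).

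The lists of growth and repair genes did not pass the test at 3 d, but single members did. Of 41 growth factors and receptors 10 rose and 5 fell at 3 d, with Igf1 at 2.47 ± 0.19 and Tgfb1 at 2.11 ± 0.22 (12 and 6 adjusted over the list alone; list adjusted p = 0.325). Of 27 axon growth genes 10 rose and 5 fell, with Tubb6 at 2.35 and Atf3 at 1.18 (12 and 9 adjusted over the list alone; adjusted p = 0.299). Of 21 neural progenitor genes 8 rose, with Nes (nestin) at 1.66 ± 0.13 (8 adjusted over the list alone; adjusted p = 0.149). Of 30 immediate early genes 5 rose and 4 fell (5 and 4 adjusted over the list alone; median -0.12, mean 0.03, adjusted p = 0.975). Of 15 reference genes 3 rose and 0 fell at 3 d, among them Gusb (1.11 ± 0.18) and Rplp0 (0.80 ± 0.14), and 3 rose and 3 fell at 14 d, with Gusb at 1.25 ± 0.18, Rplp0 at 0.54 ± 0.14, Tfrc at -0.69 ± 0.17 and Pgk1 at -0.64 ± 0.14 (3 and 0, and 3 and 4, adjusted over the list alone), while the list passed at neither time (adjusted p = 0.656 and 0.91). The 63 ribosomal protein genes, a group chosen after its values were seen, had medians of 0.47 and 0.23 at 3 d and 0.27 and 0.19 at 14 d in young and aged rats.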
